A study of Mus musculus with 21 samples.

How the data were processed

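Total RNA was measured by RNA sequencing in primary neurosphere cells from the adult mouse ventricular-subventricular zone, the neurogenic niche that lines the lateral ventricles. Neurospheres are free-floating colonies that neural stem and progenitor cells form in the presence of EGF and FGF2. Per the labels, cells of the first passage were transfected with siRNA and collected after 48 hours. The 21 libraries form 7 groups of 3: a control and a knockdown group for each of Pbx1, Tcf3 and Tcf4, and untransfected wild-type cells. Each knockdown has its own control group, which received a non-targeting siRNA, so no control library serves more than 1 knockdown comparison. Per the labels' protocols, libraries were made with a stranded total RNA kit. The labels do not say whether the 3 replicates of a group are separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

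The deposited table holds 21672 genes and 1 column per library, with gene symbols, Ensembl identifiers, positions on mm10 and pathway terms. FastQC, Trimmomatic 0.39, STAR 2.7.10a, featureCounts 2.0.3 and DESeq2 1.36.0 are named in the submitters' processing notes, with no settings. The name of the deposited table calls the values normalized, and they are whole numbers on a normalized score scale rather than read counts. The low values show how the authors made them. In several libraries some small whole numbers never occur and in others some occur too often, as when read counts are divided by a library factor and rounded. Where 1 read is worth less than 1, 2 read numbers can share 1 value, so reads cannot be restored exactly in those libraries and no count-based test was run. The choice between a count test and limma had been tied to the unit, and the rounded normalized values called for limma. The table lists no gene whose values sum to less than 3. It holds 0 of 13 mitochondrially encoded genes, and whether they were dropped, whether duplicate reads were removed and whether strand was used in counting are not given in the sources used here. Without a stated strand, overlapping and antisense genes cannot be told apart, and reads shared by paralogs may be split between them.

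The factor behind each library was estimated from the steps between low values, by finding the factor whose rounded multiples match the values that occur. In 7 simulated libraries the estimate was off by at most 0.0%. The value of 1 read lay between 0.8772 and 1.4628, and the totals of the values (5622522 to 6187344 per library) correspond to 4140126 to 6505334 assigned reads. At a value of 10, the lowest that the filter accepts, counting error is about the size of the square root of the reads, so changes in genes of low level are poorly resolved. Replicate pairs were compared with the noise that counting gives. Over genes with a mean of at least 50 the mean squared difference was 0.877 times that noise for Tcf4 knockdown replicates 1 and 2. It was 0.968 times for Pbx1 knockdown replicates 1 and 3. Other pairs of siRNA groups lay between 1.033 and 2.696 times, and untransfected pairs between 9.036 and 10.672 times. Among the 554 most abundant genes all pairs differed by more than counting noise (lowest ratio 1.549). Technical differences between libraries can also exceed counting noise, so these ratios cannot tell whether the replicates are independent. Every library was kept as a separate replicate. The effect of averaging the pairs below counting noise over genes with a mean of at least 50 is among the alternatives.

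Values were transformed as log2(value + 1) and tested with limma 3.58.1 in R 4.3.3, with a mean for each of the 7 groups, all 21 libraries sharing 1 estimate of the spread per gene, and moderated statistics with a trend on mean level and robust weights. A fold change is on the log2(value + 1) scale and understates the change of low genes. Genes with a value of at least 10 in at least 3 libraries were tested, which left 15223 genes (12835 protein-coding) and set aside 6449. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene with an adjusted p under 0.05 is said to have risen, fallen or changed. The 7 comparisons were each knockdown against its own control, the mean of the 9 control libraries against the untransfected libraries, and the 3 differences between knockdown responses. The samples' groups, these comparisons, the tests, the filter, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined.

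The 25 gene lists cover TALE homeodomain factors, E-proteins and Id proteins, astrocytes and quiescent neural stem cells, activated stem cells and transit-amplifying progenitors, neuroblasts and neurons, oligodendrocyte precursors, oligodendrocytes, ependymal cells, microglia, endothelial and mural cells, fibroblasts and mesenchymal cells, G1/S phase, G2/M phase, the Notch pathway, BMP and TGF-beta response, Wnt response, Hedgehog response, interferon response, p53 response, unfolded protein and integrated stress response, cholesterol biosynthesis, hypoxia and glycolysis, immediate early genes, mitochondrially encoded genes, and extracellular matrix and adhesion. Of these, 23 were tested. The microglia list had 2 measured members of 14 and the mitochondrially encoded list 0 of 13, below the minimum of 3, and neither was tested. In the hypoxia and glycolysis list Aldoa appears under 2 identifiers, which gives 24 entries for 23 genes. Lists were tested against all other genes with camera (limma) at a preset correlation between genes of 0.01, with an adjustment over the lists of a comparison, and again with the correlation estimated from the data. The fry test (limma), which asks whether a list's genes move on balance 1 way without reference to other genes, is given as a count. At an adjusted p under 0.05, fry called 4 of the 23 lists with Pbx1, 5 with Tcf3 and 7 with Tcf4 siRNA. Between control siRNA and untransfected cells it called 10. For the differences it called 5 (Tcf3 and Tcf4), 1 (Pbx1 and Tcf3) and 6 (Pbx1 and Tcf4). Pathway terms in the deposited table were not among the fixed tests and were chosen after the data were seen. They were limited to terms with 10 to 300 measured members.

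Named genes follow a rule with 5 parts: the targeted genes in every comparison; the 10 largest rises and the 10 largest falls among protein-coding genes with an adjusted p under 0.05, a mean of at least 50 over the libraries of the comparison and replicate ranges that do not overlap; the 4 members with the smallest adjusted p in each list that camera called, and all TALE, E-protein and Id genes; up to 10 shared genes per pair of knockdowns with the largest smaller fold change; and the 5 genes with the smallest adjusted p for each difference. Values are printed mainly for genes whose call held with each library left out, and the rest are counted. List members named beyond the first 4, and changed members of lists without a call, were chosen after their values were seen. Positions are from the deposited table, whose identifiers were found in the GENCODE annotation of the same build for 99.86% of genes.

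The alternatives were another scaling (trimmed mean of M values), no filter or a minimum of 50, a pseudocount of 0.5 or 4, the replicate number as a block, only the libraries of the comparison, each library left out in turn, each control group on its own against untransfected cells, and the estimated correlation for lists. Alternatives added after the data were seen left out the untransfected libraries or 2 of them, weighted libraries by quality, removed a trend on the value per exon base, left out genes with a high value per exon base, averaged the closest replicate pairs, or left the targeted gene out of its list. The gene test was tested on simulated counts drawn at the real means and depths and passed through the same rounding. Changes were given only to genes with a mean of at least 50, so recovery in lower genes is not covered. For the Pbx1 comparison the test recovered 25, 40, 47 and 50 of 50 genes changed by 1.25, 1.5, 2 and 4-fold and called 2 unchanged genes. For Tcf3 it recovered 31, 44, 50 and 50 and called 11 unchanged genes, and for Tcf4 it recovered 26, 45, 48 and 50 and called 0, each among 15358 genes tested. In the Tcf4 simulation camera called the raised set (adjusted p = 4.88e-97) and 0 of 100 unchanged sets, over 15339 genes. Genes were drawn independently there, whereas the estimated correlation in the real data was, for instance, 0.659 in the G2/M phase list. The simulation therefore does not show how often camera calls unchanged lists of correlated genes.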

Results

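The data are RNA sequencing profiles of mouse neural stem and progenitor cells, grown as neurospheres from the adult ventricular-subventricular zone and treated for 48 hours with siRNA against 1 of 3 transcription factors. Pbx1 is a TALE-class homeodomain factor. Tcf3 (also called E2A) and Tcf4 (E2-2) are E-proteins, class I basic helix-loop-helix factors that bind DNA as dimers and are held off DNA by Id proteins. Each knockdown had 3 libraries and its own 3 control libraries with a non-targeting siRNA, and 3 libraries came from untransfected cells, 21 in all. Normalized values summed to between 5622522 and 6187344 per library. Tcf3 knockdown replicate 1 was the shallowest library, at an estimated 4140126 assigned reads, and the other 20 libraries held 5327323 to 6505334. The comparisons ask which genes change with each siRNA in these cells, which changes the siRNAs share, and how control siRNA cells differed from untransfected cells. The samples hold 1 knockdown group per factor, so loss of the factor and other effects of its siRNA cannot be told apart.

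Each siRNA lowered its own target in all 3 knockdown libraries. Pbx1 (ENSMUSG00000052534, chromosome 1, 168119364 to 168432270 on the minus strand of mm10) had a normalized value of 452 ± 41.9 (SD, n = 3) after Pbx1 siRNA and 1310 ± 28.9 (n = 3) in its controls, a log2 fold change of -1.54 (SE 0.066, limma adjusted p = 1.59e-13). The 3 knockdown libraries read 488, 462 and 406, and the 3 controls 1298, 1289 and 1343. Tcf3 (ENSMUSG00000020167, chromosome 10, 80409514 to 80433647, minus strand) read 652, 576 and 555 after Tcf3 siRNA and 1078, 1017 and 1122 in its controls, a log2 fold change of -0.85 (SE 0.060, adjusted p = 8.39e-09). Tcf4 (ENSMUSG00000053477, chromosome 18, 69343356 to 69689079, plus strand) read 1619, 1533 and 1854 after Tcf4 siRNA and 3534, 3332 and 3547 in its controls, a log2 fold change of -1.06 (SE 0.070, adjusted p = 1.65e-09). The remaining level was 34.5% of control for Pbx1, 55.4% for Tcf3 and 48.0% for Tcf4. No siRNA gave a call for either of the other targets. Adjusted p was 0.989 for Tcf3 and 0.821 for Tcf4 after Pbx1 siRNA, 0.744 for Pbx1 and 0.536 for Tcf4 after Tcf3 siRNA, and 0.552 for Pbx1 and 0.954 for Tcf3 after Tcf4 siRNA. In untransfected cells Pbx1 read 1461 ± 170, Tcf3 1080 ± 84.2 and Tcf4 4352 ± 475 (SD, n = 3 each).

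**Figure D1:**
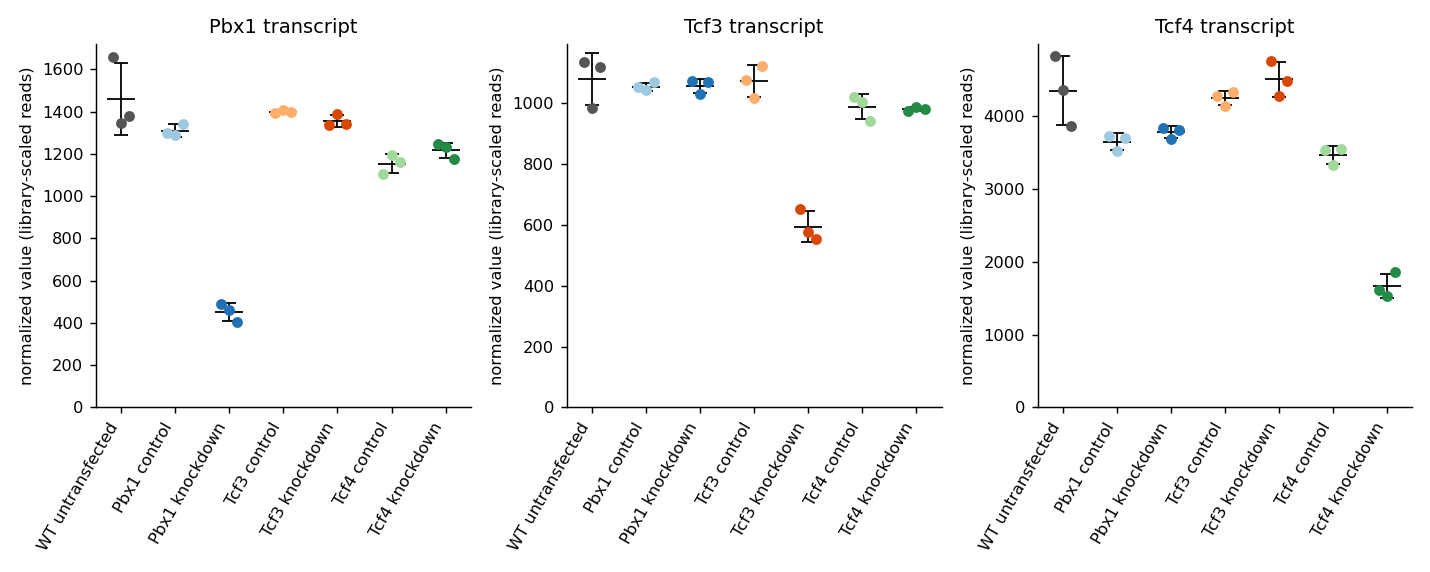
Normalized value of Pbx1, Tcf3 and Tcf4 in each of the 21 libraries, by group, with points for libraries and bars for the group mean and SD (n = 3). Each target is lowest in its own knockdown group, at 452 for Pbx1, 594.3 for Tcf3 and 1669 for Tcf4.

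The 3 siRNA experiments differed from one another more than knockdown and control did within an experiment. In a principal component analysis the first component (29.5% of the variance) set apart the 6 libraries of the Tcf4 experiment and the second (17.2%) those of the Tcf3 experiment. Knockdown and control libraries also separated. On the second component Tcf3 knockdowns scored -33.73 to -38.15 and Tcf3 controls -16.76 to -21.24. On the first, Pbx1 knockdowns (-20.02 to -27.2) lay nearer untransfected replicate 3 (-19.36) than their own controls (-8.76 to -13.84). The 3 control groups received the same kind of siRNA, yet limma called 3012 genes between the Pbx1 and Tcf3 controls, 3499 between the Pbx1 and Tcf4 controls and 2652 between the Tcf3 and Tcf4 controls. Each knockdown was compared with its own controls, as planned. Replicates of the untransfected group correlated at 0.972 to 0.976 across genes, and those of the siRNA groups at 0.986 to 0.992, where genes are not independent replicates. On the third component (9.92% of the variance) untransfected replicates 1 and 2 (-37 and -24.82) stood apart from replicate 3 (4.35).

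**Figure D2:**
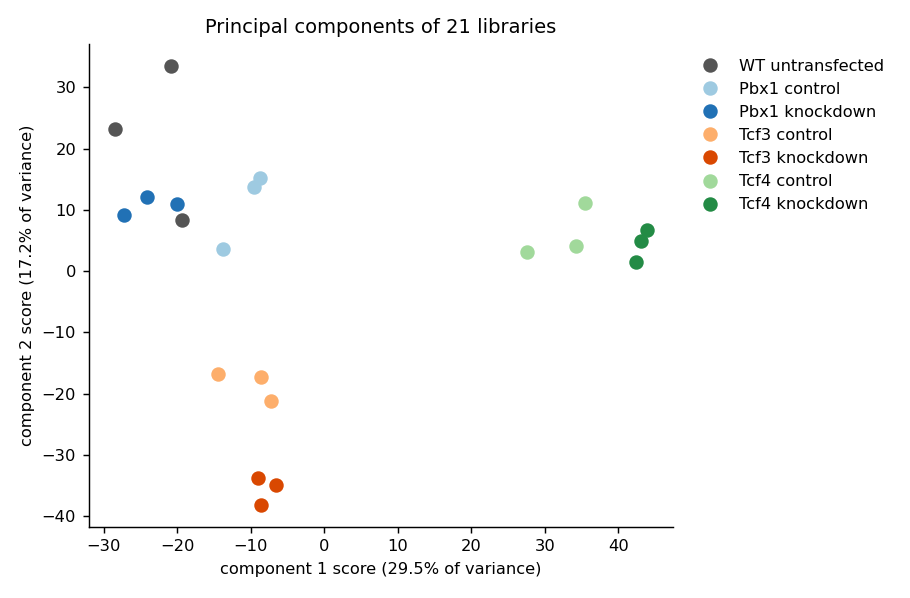
First and second principal components of log2 normalized values for the 21 libraries, with 1 point per library coloured by group. The first component separates the Tcf4 experiment from the rest and the second the Tcf3 experiment, while the Pbx1 and untransfected libraries overlap on each component.

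Knockdown of Pbx1 raised more genes than it lowered. The largest rise was that of Gna14, a G-protein alpha subunit, from 50.3 ± 13.6 in controls to 228.7 ± 32.02 (SD, n = 3 each), a log2 fold change of 2.19 (SE 0.31, adjusted p = 0.000199). Acta2, smooth muscle actin, rose from 46.0 ± 10.5 to 192 ± 46.6 (2.04, adjusted p = 0.000414), and Luzp2 rose by as much (2.04, adjusted p = 0.000253). Among genes of neurons, Scg2, which encodes a secretogranin of dense-core vesicles, rose by 1.96, the cell adhesion gene Cntn6 by 1.84, and the neurexin gene Nrxn3 by 1.38. Vstm2a (1.99) and Clmn (1.599) rose as well. Besides Pbx1 itself, the largest fall was in Htr1b, a serotonin receptor gene, at -1.30 (adjusted p = 0.000176), and Mylk, myosin light chain kinase (-1.19), the clock gene Per3 (-1.06), Adamtsl3 (-1.03) and Tns2, a tensin of focal adhesions (-0.81), fell as well. Syt1, Gabrg3 and S1pr3 were also among the 10 largest rises, and Inpp4b, Col9a3, Acot11 and Fgf1 among the largest falls, but these calls ended under 1 or more alternatives. Syt1 lost its call without each of the 6 libraries in turn, Acot11 without 5 of them, S1pr3 without 4 and Fgf1 without 3. Gabrg3 ended only where the fit held the 6 libraries of the comparison alone (adjusted p = 0.0713). Inpp4b and Col9a3 ended under 3 alternatives each, 1 of them without knockdown replicate 3 (0.0682 and 0.078).

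With Pbx1 siRNA, 373 genes rose and 175 fell, 548 of the 15223 tested (3.60%), with a median absolute change of 0.49 among them. In limma 101 rose and 13 fell by 1 or more on the log2 scale. All 548 had replicate ranges that did not overlap, as did 25.4% of all genes tested, where chance gives 10% for 3 against 3. The count was 340 without control replicate 1, 310 without control replicate 2, 283 without knockdown replicate 1 and 202 without knockdown replicate 3. It was 1707 with the 6 libraries of the comparison alone and 1499 without the untransfected libraries, which varied more than the rest.

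Among the 11 TALE factors, 4 changed with Pbx1 siRNA. Besides Pbx1 itself, Pknox1 (Prep1), whose protein binds DNA together with Pbx proteins, rose from 579 ± 30.3 to 814 ± 12.5 (log2 0.49, adjusted p = 4.63e-06), Pknox2 rose by 0.30 and Pbx3 changed by -0.29. The call of Pknox2 ended without knockdown replicate 3 (adjusted p = 0.0698), and that of Pbx3 without control replicate 2 (0.0999), control replicate 3 (0.0513) or knockdown replicate 3 (0.157). The other 7 TALE genes had adjusted p from 0.0893 to 0.993. Of the 7 E-protein and Id genes, Id4 rose from 83.0 ± 3.61 to 185 ± 21.9 (1.14, adjusted p = 0.0102), a call that ended without knockdown replicate 3 (0.0699). Neither list was called as a whole (camera adjusted p = 0.997 and 0.36).

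Camera called 5 of the 23 lists with Pbx1 siRNA, and none of the 5 calls held with an estimated correlation between genes. Neuroblast and neuron genes were higher, with 5 of 25 measured members rising and 0 falling (6 and 1 adjusted over the list alone, adjusted p = 8.13e-05, and adjusted p = 0.0871 with an estimated correlation). Elavl3, a neuronal RNA-binding protein gene, rose by 0.59 (adjusted p = 0.000109), Nrxn3 by 1.38 and the axon guidance receptor gene Robo2 by 0.76, with Syt1 and Tubb3 the other members. Fibroblast and mesenchymal genes were higher, with 3 of 10 rising, Acta2, Tagln (1.68) and Thbs1 (1.35), and 3 adjusted over the list alone (adjusted p = 0.00342, and adjusted p = 0.0778 with an estimated correlation). Extracellular matrix and adhesion genes were higher, with 4 of 25 rising and 6 adjusted over the list alone (adjusted p = 8.03e-05, and adjusted p = 0.511 with an estimated correlation). These were the laminin genes Lama4 (1.248, adjusted p = 4.3e-07) and Lamb1 (0.82) and the collagen IV genes Col4a1 (1.08, adjusted p = 1.02e-05) and Col4a2 (0.65, ended without knockdown replicate 3, 0.0517), subunits of basement membranes.

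The DNA replication genes of the G1/S phase list were lower after Pbx1 siRNA by small amounts, with a median log2 change of -0.15 over 41 members (adjusted p = 1.53e-12, and adjusted p = 0.38 with an estimated correlation). Of these 2 fell, the recombinase gene Rad51 and the flap endonuclease gene Fen1, neither of which kept the call with each library left out, and 18 fell when adjusted over the list alone. The G2/M phase list had a median of -0.10 (adjusted p = 8.03e-05, and adjusted p = 0.846 with an estimated correlation), with 0 of 52 members called by limma and 2 lower at an unadjusted p under 0.05. The hypoxia and glycolysis list was not called (adjusted p = 0.0747), and its members Pfkp (0.78), the neuronal glucose transporter gene Slc2a3 (0.95) and Ndrg1 (1.07) rose. In lists without a call, from an adjusted p of 0.285 upward, Klf4 (0.87, immediate early) and Cnp (0.37, oligodendrocyte) rose, and Insm1 (-0.69, activated stem cell) and Tcf7 (-0.52, Wnt) fell. Dll4 (Notch), Bmpr1b and Id4 (BMP and TGF-beta), Gli2 (Hedgehog) and Ddit4l (p53) also rose and Prom1 (astrocyte and quiescent stem cell) fell. In limma 0 of 13 oligodendrocyte precursor genes changed, with 3 higher and 1 lower at an unadjusted p under 0.05. The corresponding counts were 0 of 9 ependymal genes (0 higher, 0 lower), 0 of 4 endothelial and mural genes (1 and 0), 0 of 22 interferon response genes (0 and 0), 0 of 26 stress response genes (0 and 1) and 0 of 25 cholesterol genes (0 and 1). Of the 31 list members called with Pbx1 siRNA, 18 kept the call with each library left out. The call was lost for 7 without control replicate 1, 8 without control 2, 7 without control 3, 8 without knockdown 1, 6 without knockdown 2 and 13 without knockdown 3.

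Knockdown of Tcf3 raised and lowered similar numbers of genes, and many DNA replication genes were among those that fell by small amounts. Frmpd4, which encodes a scaffold protein of excitatory synapses, rose from 19.7 ± 5.13 in controls to 93.7 ± 21.4 (SD, n = 3 each), a log2 fold change of 2.20 (SE 0.27, adjusted p = 5.82e-05). Gad2, an enzyme of GABA synthesis, rose from 62.7 ± 10.6 to 157 ± 9.54 (1.32, adjusted p = 0.00287). Vstm2a (1.63), Crispld2 (1.595), Ahnak2 (1.52), the amino acid transporter gene Slc7a8 (1.45), Dusp15 (1.358) and the small heat shock protein gene Cryab (1.27) rose too. Plscr4, a phospholipid scramblase gene, fell by 1.17 (adjusted p = 0.000679), and Sgms2, a sphingomyelin synthase gene, fell by 0.84. Rflna (-0.70), Zc3hav1l (-0.67) and Arl5b (-0.67) fell as well. Lgals3bp and Gstt3 among the 10 largest rises, and Igf1, Adamts3, Ebf3 and Asxl3 among the 10 largest falls, lost their calls under 1 or more alternatives. Igf1 and Adamts3 lost theirs without each of the 6 libraries in turn, Asxl3 without 5 of them and Ebf3 without 3. Gstt3 ended without control replicate 1 (adjusted p = 0.0598), and Lgals3bp ended with the 6 libraries of the comparison alone (0.123).

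With Tcf3 siRNA, 478 genes rose and 481 fell, 959 in all (6.30% of those tested), with a median absolute change of 0.35. In limma 53 rose and 19 fell by 1 or more on the log2 scale. Of the 959, 940 had replicate ranges that did not overlap, as did 26.8% of all genes. The count fell to 339 without control replicate 1, 572 without control 2, 612 without control 3, 575 without knockdown 1, 513 without knockdown 2 and 540 without knockdown 3. It was 1616 with the 6 libraries of the comparison alone and 2353 without the untransfected libraries.

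Camera called 8 of the 23 lists with Tcf3 siRNA, and none of the 8 calls held with an estimated correlation. The broadest was the G1/S phase list, in which 19 of 41 members fell and 0 rose, 32 fell when adjusted over the list alone, and the median log2 change was -0.21 (adjusted p = 2.06e-19, and adjusted p = 0.40 with an estimated correlation). Wdr76 (-0.36, adjusted p = 0.00208), Rad51 (-0.365, adjusted p = 0.00215), Dtl (-0.38), a substrate receptor of a replication-linked ubiquitin ligase, and the polymerase delta subunit gene Pold3 (-0.24) kept their calls with each library left out, and the other 15 did not. Those included the replication licensing genes Mcm2, Mcm5, Mcm6 and Cdc6. In the G2/M phase list 2 of 52 fell, Cdca2 and Cdc25c, and 0 when adjusted over the list alone by limma, with 8 lower at an unadjusted p under 0.05 (adjusted p = 0.00252, and adjusted p = 0.784 with an estimated correlation). That list call ended without control replicate 1 (adjusted p = 0.0698) or control replicate 3 (0.0666).

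Camera called 6 lists as higher with Tcf3 siRNA. In the p53 response list 7 of 22 members rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.000108, and adjusted p = 0.40 with an estimated correlation). The DNA repair gene Ercc5 rose by 0.33 (adjusted p = 0.000478) and the apoptosis gene Bbc3 by 0.41 (ended without control replicate 1, 0.0856), with Ano3, Ddit4l, Btg2, Fas and Aen the other rising members and Zmat3 the falling one. In the hypoxia and glycolysis list 3 of 24 rose, Slc2a3 (0.86, adjusted p = 0.00058), Adm and Gpi1, and 4 adjusted over the list alone (adjusted p = 0.0054, and adjusted p = 0.40 with an estimated correlation). In the interferon response list 2 of 22 rose, the double-stranded RNA sensors Eif2ak2 (PKR) and Ddx58 (RIG-I), and 12 adjusted over the list alone, with a median of 0.64 (adjusted p = 1.16e-06, and adjusted p = 0.40 with an estimated correlation). Of the immediate early genes 3 of 24 rose, Jun, Klf4 and Dusp6, and 6 adjusted over the list alone (adjusted p = 0.000323, and adjusted p = 0.619 with an estimated correlation). Extracellular matrix and adhesion genes were higher, with 7 of 25 rising (10, and 1 falling, adjusted over the list alone), among them Lama2, Lama4 and Sparc (adjusted p = 2.1e-05, and adjusted p = 0.40 with an estimated correlation). Of the astrocyte and quiescent stem cell genes 3 of 24 rose, the glutamate transporter gene Slc1a2, Aldoc and Slc6a11, and the stem cell surface gene Prom1 fell by 0.66 (4 and 1 adjusted over the list alone, adjusted p = 0.0054, and adjusted p = 0.619 with an estimated correlation).

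The remaining lists were not called with Tcf3 siRNA, with adjusted p of 0.0517 for Notch and for cholesterol biosynthesis and 0.264 to 0.985 for the others. In the neuroblast and neuron list Gad2, Nsg2 (0.54, adjusted p = 0.00226) and Robo2 rose and Nsg1 fell. In the activated stem cell list Hes6, Dll1 and Btg2 rose and Rrm2 and Fbxo5 fell. Among stress response genes Shmt2, the mitochondrial serine hydroxymethyltransferase gene, fell by 0.35 (adjusted p = 0.00232), as did Phgdh and Asns, all of serine, glycine or asparagine synthesis. Sox8 rose and Lhfpl3 fell (oligodendrocyte precursor), Axin2 rose and Sfrp2 fell (Wnt), Dll1 rose (Notch), and Fn1 fell (fibroblast). Pbx3 changed by -0.29 (adjusted p = 0.0171), a call that ended without control replicate 2 (0.0572), control 3 (0.055) or knockdown 2 (0.101), and the other 10 TALE genes had adjusted p from 0.119 to 0.954. Of the E-protein and Id genes Tcf3 alone passed, and Id1 had a log2 change of 0.45 (adjusted p = 0.0953). In limma 0 of 16 oligodendrocyte genes changed, with 3 higher and 1 lower at an unadjusted p under 0.05, and the corresponding counts were 0 of 9 ependymal genes (2 higher, 0 lower), 0 of 4 endothelial and mural genes (1 and 0), 0 of 15 BMP and TGF-beta genes (3 and 0), 0 of 10 Hedgehog genes (0 and 1) and 0 of 25 cholesterol genes (0 and 2). Of the 65 list members called with Tcf3 siRNA, 11 kept the call with each library left out. The call was lost for 45 without control replicate 1, 35 without control 2, 31 without control 3, 32 without knockdown 1, 35 without knockdown 2 and 35 without knockdown 3.

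Knockdown of Tcf4 lowered Id2 and Id3, which encode inhibitors of E-proteins, and raised many genes of cholesterol biosynthesis by small amounts. St6galnac5, a sialyltransferase gene, rose from 38.7 ± 5.51 in controls to 217 ± 20.1 (SD, n = 3 each), a log2 fold change of 2.46 (SE 0.20, adjusted p = 1.03e-07). Dio2, which encodes the deiodinase that activates thyroid hormone, rose from 198 ± 7.81 to 676 ± 4.62 (1.77, adjusted p = 6.68e-06). Snap25 (1.82) and Cplx1 (1.64), both of synaptic vesicle fusion, the receptor genes Grin2c (1.81) and Gabra4 (1.47), the sodium pump gene Atp1a3 (1.42), Chchd10 (1.95) and the cystine transporter gene Slc7a11 (1.40) rose. Ryr3, an intracellular calcium channel gene, fell from 249 ± 28.5 to 87.0 ± 17.4 (-1.52, adjusted p = 4.22e-07), and Id2 from 234 ± 5.57 to 99.3 ± 29.9 (-1.27, adjusted p = 1.03e-06). Grin2a (-1.80), the oligodendrocyte transcription factor gene Zfp488 (-1.73), Plxnb3 (-1.64), the oligodendrocyte lineage connexin gene Gjc3 (-1.62), Prdm1 (-1.45) and Htr1b (-1.39) fell as well. Thy1 among the 10 largest rises lost its call without control replicate 2 (adjusted p = 0.0554), and Ptpre among the largest falls without control replicate 3 (0.0526) or knockdown replicate 2 (0.0595). Cpxm2, the remaining one of those falls, lost its call without each of the 6 libraries.

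With Tcf4 siRNA, 621 genes rose and 528 fell, 1149 in all (7.55% of those tested), with a median absolute change of 0.39. In limma 88 rose and 57 fell by 1 or more on the log2 scale. Of the 1149, 1141 had replicate ranges that did not overlap, as did 34.5% of all genes. The count was 672 without control replicate 2, 676 without control 3, 673 without knockdown 1, 624 without knockdown 2 and 729 without knockdown 3. It was 3061 with the 6 libraries of the comparison alone and 2426 without the untransfected libraries.

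Camera called 9 of the 23 lists with Tcf4 siRNA. The E-protein and Id list was lower, with 4 of 7 members falling and 4 adjusted over the list alone (adjusted p = 2.3e-06, and adjusted p = 0.0262 with an estimated correlation). These were Tcf4 itself, Id2 (-1.27), Id3 (-0.94, adjusted p = 0.000148) and Id1 (-0.61), and the call of Id1 ended without control replicate 2 (0.107) or knockdown replicate 2 (0.132). Without Tcf4, the targeted gene, the list had an adjusted p of 0.00052, and of 0.126 with an estimated correlation. Cholesterol biosynthesis genes were higher, with 19 of 25 rising, 23 adjusted over the list alone, 0 falling and a median of 0.38 (adjusted p = 4.06e-17, and adjusted p = 0.126 with an estimated correlation). Lss (lanosterol synthase) rose by 0.77, Hsd17b7 by 0.63, Mvd by 0.57, Mvk by 0.44, Hmgcr, the rate-limiting enzyme, by 0.44 and Sqle by 0.33, and 8 of the 19 kept their calls with each library left out. Astrocyte and quiescent stem cell genes were higher, with 9 of 24 rising and Id3 falling, 15 and 2 adjusted over the list alone (adjusted p = 2.3e-06, and adjusted p = 0.253 with an estimated correlation). The glutamate transporter genes Slc1a2 (0.55) and Slc1a3 (0.28) and the metallothionein gene Mt3 (0.40) were among them. TALE genes were not called as a list (adjusted p = 0.154), and of the 11 Tgif1, a repressor of TGF-beta response, fell by 0.53 (adjusted p = 0.0027), where the other 10 had adjusted p from 0.0902 to 0.933.

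Other called lists with Tcf4 siRNA held genes of neurons, metabolism and stress. Of the neuroblast and neuron genes 5 of 25 rose, 6 and 2 falling adjusted over the list alone, led by Elavl3 (0.88, adjusted p = 3.82e-07), Snap25, Nrxn3 (1.24) and Stmn3 (0.49), with Sp8 the remaining member (adjusted p = 0.0262, and adjusted p = 0.285 with an estimated correlation). That list call also ended without control replicate 1 (0.0957), without knockdown replicate 3 (0.0586), with the 6 libraries of the comparison alone (0.241), without the untransfected libraries (0.0966), with a filter at 50 (0.0824) and with the trend on value per exon base removed (0.121). Of the unfolded protein and integrated stress response genes 7 of 26 rose, 9 adjusted over the list alone, among them the amino acid stress genes Atf5 (0.39), Asns (0.54), Mthfd2 (0.46), Slc7a11 (1.40) and Slc3a2 (0.27) (adjusted p = 3.73e-05, and adjusted p = 0.126 with an estimated correlation). In the hypoxia and glycolysis list 8 of 24 rose, 9 and 1 falling adjusted over the list alone, among them P4ha2 (1.18), Vegfa (0.78), Egln3 (0.59), Higd1a (0.49) and Pfkp (0.45) (adjusted p = 6.8e-05, and adjusted p = 0.126 with an estimated correlation). In the interferon response list 3 of 22 rose, Stat2, Eif2ak2 and Oasl2, and 5 adjusted over the list alone (adjusted p = 7.41e-05, and adjusted p = 0.313 with an estimated correlation). Of the immediate early genes 2 of 24 fell, Klf4 (-0.80, adjusted p = 5.48e-05) and Dusp1, and 2 adjusted over the list alone (adjusted p = 0.00145, and adjusted p = 0.452 with an estimated correlation). The G2/M phase list was higher by a median of 0.11 (adjusted p = 0.000303, and adjusted p = 0.698 with an estimated correlation), a call that ended without control replicate 3 (0.057), with 0 of 52 members called by limma and 6 higher and 1 lower at an unadjusted p under 0.05.

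The remaining lists were not called with Tcf4 siRNA, with adjusted p from 0.0795 for oligodendrocyte precursor genes to 0.725. The proneural gene Ascl1 rose by 0.31 (adjusted p = 0.00156) with Hes6, and the Notch ligand gene Dll1 fell by 0.36 (adjusted p = 0.00372) with Btg2 (activated stem cell list). Sox6 (-0.37) fell and Cspg5 rose among oligodendrocyte precursor genes, and Tspan2 rose among oligodendrocyte genes. Id1, Id2 and Id3 fell in the BMP and TGF-beta list, Cdon (-0.39) and Ptch1 fell and Gli2 rose in the Hedgehog list, and Dll1 fell in the Notch list. Cdh4 (0.28), Timp4 (0.46) and Cspg5 rose and Lamb1 fell among extracellular matrix genes. Aen rose and Zmat3 and Btg2 fell in the p53 list, Fam183b rose and Ccdc153 fell among ependymal genes, and Tek fell among endothelial and mural genes. In limma 0 of 41 G1/S phase genes changed, with a median of 0.01 and 1 higher and 0 lower at an unadjusted p under 0.05, and the corresponding counts were 0 of 10 fibroblast genes (0 higher, 1 lower) and 0 of 14 Wnt genes (0 and 1). Of the 76 list members called with Tcf4 siRNA, 36 kept the call with each library left out. The call was lost for 15 without control replicate 1, 29 without control 2, 33 without control 3, 29 without knockdown 1, 35 without knockdown 2 and 27 without knockdown 3.

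**Figure D3:**
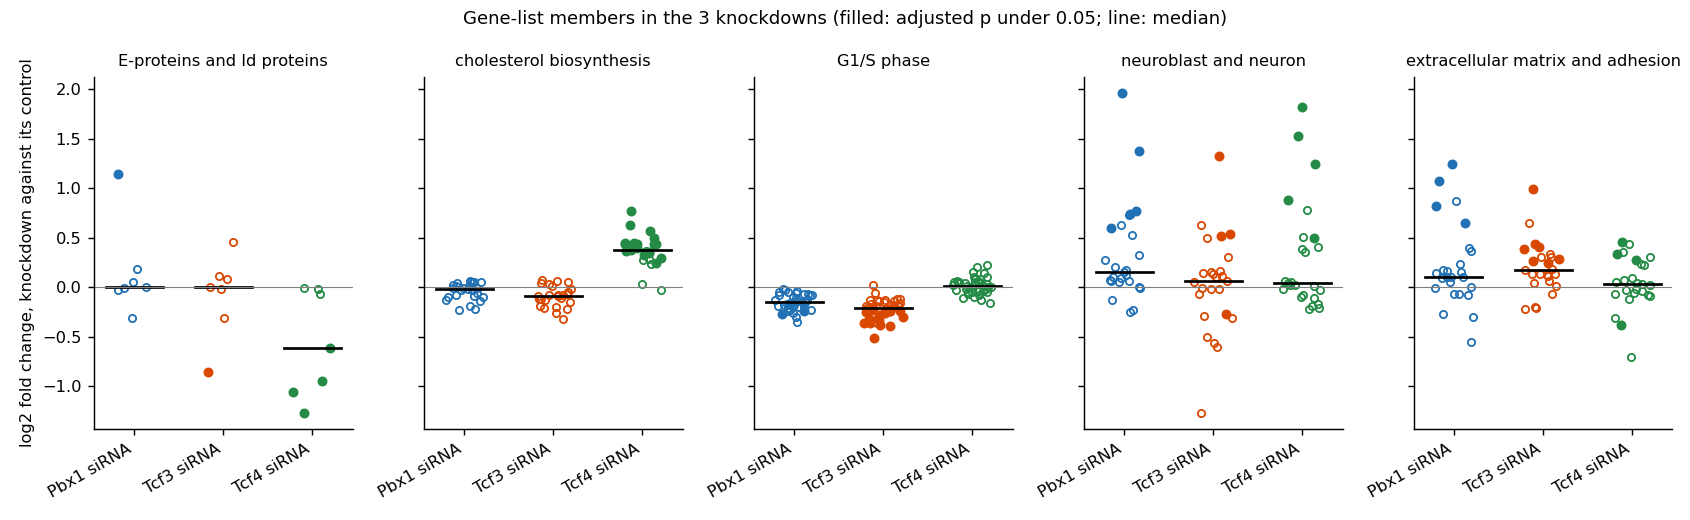
Log2 fold change of each member of 5 gene lists after Pbx1, Tcf3 and Tcf4 siRNA, with filled points for genes with an adjusted p under 0.05 and a line at the median of the list. G1/S phase genes have medians of -0.152 with Pbx1, -0.206 with Tcf3 and 0.009 with Tcf4 siRNA, and cholesterol biosynthesis genes a median of 0.378 with Tcf4 siRNA.

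By count, each pair of knockdowns shared more rising than falling genes, a difference that was not tested. Tcf3 and Tcf4 siRNA both raised Mamdc2 (log2 1.13 and 0.84), the synaptic vesicle gene Sv2a (0.86 and 0.84), the hedgehog ligand gene Dhh (0.83 and 0.90), Ankrd29 (0.86 and 0.79), Gm2115 (0.87 and 0.72) and Emp2 (0.70 and 0.78). Pbx1 and Tcf3 siRNA both raised Vstm2a (1.99 and 1.63), Slc2a3 (0.95 and 0.86) and Reps2 (1.03 and 0.80). Pbx1 and Tcf4 siRNA both raised Nrxn3 (1.38 and 1.24), Stk33 (0.79 and 1.022), Rab11fip5 (0.70 and 0.96) and Myorg (0.76 and 0.73) and lowered Htr1b (-1.30 and -1.39) and Tns2 (-0.81 and -1.07). All 3 siRNAs raised Frmpd1 (1.018, 0.69 and 0.57 for Pbx1, Tcf3 and Tcf4).

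In all, 109 genes rose and 44 fell with both Tcf3 and Tcf4 siRNA, where independent lists would share 19.5 and 16.7. For Pbx1 and Tcf3, 75 rose and 29 fell with both (11.7 and 5.53 for independent lists), and for Pbx1 and Tcf4, 70 and 14 (15.2 and 6.07). With all 3 siRNAs 19 genes rose and 2 fell. Opposite changes were found in 34 genes for Tcf3 and Tcf4 (36.2 for independent lists), 14 for Pbx1 and Tcf3 (17.3) and 37 for Pbx1 and Tcf4 (20.1). Each of these genes passed the test of the difference. That test comes from the same fit, so genes called in opposite directions are nearly bound to pass it, and it adds no support. Across the 15223 genes, which are not independent replicates, fold changes correlated at r = 0.191 (Spearman 0.18) for Tcf3 and Tcf4, 0.162 (0.17) for Pbx1 and Tcf3 and 0.077 (0.028) for Pbx1 and Tcf4. The shared count of Tcf3 and Tcf4, 153, fell to 67 without Tcf3 control replicate 1, 101, 97 and 85 without Tcf3 knockdown 1, 2 and 3, 96 without Tcf4 control 2 and 89 without Tcf4 knockdown 2. That of Pbx1 and Tcf3, 104, fell to 62 without Pbx1 control 2, 58 and 44 without Pbx1 knockdown 1 and 3, 49 and 68 without Tcf3 control 1 and 3, and 66 and 64 without Tcf3 knockdown 1 and 2. That of Pbx1 and Tcf4, 84, fell to 49 without Pbx1 control 3, 53 without Pbx1 knockdown 1 and 43 without Pbx1 knockdown 3.

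The responses to Tcf3 and Tcf4 siRNA differed in named genes. Each siRNA was used in 1 experiment and left a different share of its target. A difference between factors therefore cannot be told apart from a difference between experiments or in the depth of knockdown. Wnt5a, a secreted Wnt ligand gene, rose by 0.30 with Tcf3 siRNA and fell by 0.68 with Tcf4 siRNA (difference 0.98, SE 0.090, adjusted p = 4.96e-07). The adaptor gene Shc4 rose by 0.45 and fell by 0.44 (difference 0.89, adjusted p = 4.96e-07), and Tmcc1 fell by 0.52 with Tcf4 siRNA (difference 0.60, adjusted p = 2.33e-05). Klf4, a reprogramming factor gene chosen after its values were seen, differed by 1.23 (adjusted p = 8.16e-05), and it fell by 0.80 with Tcf4 siRNA. Elavl3 was lower by 0.82 with Tcf3 siRNA relative to Tcf4 siRNA (log2 difference -0.82, adjusted p = 0.000255). Camera called 10 lists for this difference, and 0 held with an estimated correlation. Cholesterol biosynthesis genes stood lower with Tcf3 than with Tcf4 siRNA, 10 of 25 members by the test of the difference (list adjusted p = 4.61e-17, and adjusted p = 0.207 with an estimated correlation). G1/S phase genes were lower too, 3 of 41 members by that test and 18 adjusted over the list alone (list adjusted p = 2.68e-14, and adjusted p = 0.207 with an estimated correlation). Of immediate early genes 3 of 24 were higher with Tcf3 siRNA (list adjusted p = 6.72e-08, and adjusted p = 0.228 with an estimated correlation). In all 466 genes differed between the Tcf3 and Tcf4 responses, 265 higher and 201 lower with Tcf3 siRNA. Without single libraries the count was 219 (Tcf3 control 1), 243 and 304 (Tcf3 knockdown 2 and 3), 248 and 241 (Tcf4 control 2 and 3) and 240, 224 and 277 (Tcf4 knockdown 1, 2 and 3).

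The response to Pbx1 siRNA differed from those to Tcf3 and Tcf4 siRNA, with the same limit that each siRNA was used in 1 experiment. Ryr3 rose by 1.12 with Pbx1 siRNA and fell by 1.52 with Tcf4 siRNA (difference 2.64, SE 0.20, adjusted p = 2.51e-08), Sncaip, whose protein binds alpha-synuclein, rose by 0.59 and fell by 0.87 (difference 1.462, adjusted p = 8.44e-08), and St6galnac5 had a difference of -3.25 (adjusted p = 1.74e-07). The call of St6galnac5 with Pbx1 siRNA alone ended without control replicate 1 (0.0646), 2 (0.135) or 3 (0.0646) or knockdown replicate 1 (0.111) or 3 (0.17). Klf4 rose by 0.87 with Pbx1 siRNA, and its difference from the Tcf4 response was 1.67 (adjusted p = 3.45e-07). Relative to Tcf3 siRNA, the transcription factor gene Nfic (log2 -0.44 with Pbx1 and 0.14 with Tcf3 siRNA, difference -0.58, adjusted p = 0.000219), Sv2a (difference -1.01) and the clock output gene Tef (difference -0.70) were lower with Pbx1 siRNA. In all 257 genes differed between Pbx1 and Tcf3 siRNA (121 higher and 136 lower with Pbx1) and 665 between Pbx1 and Tcf4 siRNA (399 and 266). Camera called 6 lists for the former, 0 with an estimated correlation (smallest adjusted p = 0.0973, fibroblast genes), and 12 for the latter, of which 2 held. Those were the fibroblast list, in which Acta2, Tagln and Thbs1 were higher with Pbx1 siRNA (list adjusted p = 0.00133, and adjusted p = 0.0318 with an estimated correlation), and the E-protein and Id list, which includes the targeted Tcf4 (list adjusted p = 2.43e-07, and adjusted p = 0.0139 with an estimated correlation).

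Single libraries moved the counts of these differences. For Pbx1 and Tcf3 siRNA, 257 fell to 123 and 105 without Pbx1 control 1 and 2, to 104, 151 and 90 without Pbx1 knockdown 1, 2 and 3, to 105 and 122 without Tcf3 control 1 and 2, and to 101 and 124 without Tcf3 knockdown 2 and 3. For Pbx1 and Tcf4 siRNA, 665 fell to 440 and 364 without Pbx1 control 1 and 2, to 418 and 320 without Pbx1 knockdown 1 and 3, to 397 and 424 without Tcf4 control 2 and 3, and to 406 and 389 without Tcf4 knockdown 1 and 2.

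Control siRNA cells differed from untransfected cells in many genes, with Mbp the largest rise and Acta2 the largest fall among protein-coding genes with a mean of at least 50 and separate ranges. Mbp, the myelin basic protein gene, stood at 160 ± 50.7 (SD, n = 9) in control libraries and 46.3 ± 22.5 (n = 3) in untransfected ones, a log2 difference of 1.82 (SE 0.23, adjusted p = 8.06e-05). The kinase gene Camk2a was higher by 1.463 (adjusted p = 2.95e-07), Hopx, a gene of quiescent stem cells, by 1.304, the phosphatase subunit gene Ppp2r2c by 1.28 and Svop by 1.14, with Fam81a (1.11), Erich3 (1.07) and Cox6b2 likewise higher. Acta2 stood at 40.0 ± 14.4 in controls and 204 ± 95.3 in untransfected cells (-2.29, adjusted p = 7.33e-06), and Tagln, another smooth muscle gene, was lower by 2.49 on the same scale (log2 -2.49, adjusted p = 1.01e-06). B3gnt5 (-0.78), Syt14 (-0.69), Trim66 (-0.64) and the inositol transporter gene Slc5a3 (-0.61, adjusted p = 7.09e-08) were lower as well. Cxcl14 and Gm19426 among the 10 largest rises, and Thbs1, Igip, Erbb4, Zbtb37 and Prune2 among the 10 largest falls, kept their calls with each library left out and lost them without untransfected replicates 1 and 2 together (adjusted p from 0.0599 to 0.222), a fit that keeps 1 untransfected library and takes the spread from the other groups. The call of Gm19426 also ended with the Pbx1 control group alone (0.0528). The controls came from 3 experiments that differed from one another by 2652 to 3499 genes, and the labels do not tie the untransfected cells to any of them, so the effect of transfection and differences between experiments cannot be told apart here.

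Limma called 1895 genes as higher and 1884 as lower in control siRNA cells, 3779 in all (24.8% of those tested), with a median absolute change of 0.32. Of these 663 had ranges that did not overlap, as did 4.62% of all genes, where chance gives 0.909% for 9 against 3. The count was 1567 with the Pbx1 control group alone, 2341 with the 12 libraries of the comparison alone, 1724 without untransfected replicates 1 and 2, which leaves 1 untransfected library, and 1020 with library weights. The fit behind the 3779 genes gives each control group its own mean, so differences between the control groups do not enter its error. Its spread comes mostly from siRNA groups, whose replicates varied less than the untransfected ones. With the 9 control libraries as a single group, limma called 443 genes over the 12 libraries. Pbx1 (-0.18, adjusted p = 0.0177) and Tcf4 (-0.20, adjusted p = 0.0135) were lower in control siRNA cells, calls that ended without untransfected replicate 1 (0.232 and 0.126) and with the Tcf3 control group alone (0.582 and 0.798), and Tcf3 did not pass (-0.06, adjusted p = 0.443).

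Camera called 12 of the 23 lists between control siRNA and untransfected cells, and none of the 12 held with an estimated correlation. Of the G2/M phase genes 28 of 52 were higher, led by Ube2c (0.81, adjusted p = 1.01e-06), Psrc1 (0.41), Gtse1 (0.30) and Cdc20 (0.37), all of mitosis (adjusted p = 3.97e-11, and adjusted p = 0.414 with an estimated correlation). Of the interferon response genes 12 of 22 were higher, led by Ifit1 (2.20, adjusted p = 0.000153), with Ifit3b (2.10), Cxcl10 (1.71) and Ifi27 (1.00) (adjusted p = 1.13e-05, and adjusted p = 0.292 with an estimated correlation). Of the p53 response genes 9 of 22 were higher, among them Bbc3 (0.52) and Pmaip1 (0.51), which promote apoptosis (adjusted p = 0.000164, and adjusted p = 0.292 with an estimated correlation), and this list call ended without untransfected replicate 3 (0.0625). Of the G1/S phase genes 9 of 41 were higher, led by Gmnn (0.73), the gene of the licensing inhibitor geminin (adjusted p = 0.000944, and adjusted p = 0.585 with an estimated correlation), a list call that ended with the Pbx1 (0.13) or the Tcf3 control group alone (0.692). Cholesterol genes were higher in 10 of 25 and lower in 1, with Mvd (0.42) first (adjusted p = 0.00019, and adjusted p = 0.507 with an estimated correlation), which ended with the Tcf4 control group alone (0.0547). Among these members, the call of Ifi27 (0.0981) and Gmnn (0.102) ended with the Pbx1 control group alone, that of Mvd (0.136) with the Tcf3 control group and that of Cxcl10 (0.0995) with the Tcf4 control group.

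The called lists between control siRNA and untransfected cells also included cell type lists. Of the oligodendrocyte genes 6 of 16 were higher, among them Mbp, Mag (2.45) and Mog (1.70), all of myelin (adjusted p = 0.00569, and adjusted p = 0.292 with an estimated correlation). Of the ependymal genes 4 of 9 were higher, among them Ccdc153 (1.67), Rsph1 (1.61) and Dynlrb2, all of motile cilia (adjusted p = 0.00736, and adjusted p = 0.241 with an estimated correlation). Both calls ended without untransfected replicates 1 and 2 together, where 1 untransfected library remains and the other groups supply the spread. Whether these 2 list calls rest on those 2 libraries therefore cannot be told. The oligodendrocyte call also ended with a filter at 50 (0.0754) or the Pbx1 control group alone (0.0511). Of the fibroblast genes 4 of 10 were lower, Acta2, Tagln, Thbs1 (-0.95) and Twist1 (adjusted p = 0.00569, and adjusted p = 0.10 with an estimated correlation). Of the BMP and TGF-beta genes 6 of 15 were lower, with Tgfbi (-1.20) first (adjusted p = 0.00736, and adjusted p = 0.10 with an estimated correlation), which ended with the Tcf3 control group alone (0.127). Of the neuroblast and neuron genes 8 of 25 were lower, with Gad2 (-1.07, and -0.088, -0.379 and -2.731 with the Pbx1, Tcf3 and Tcf4 control group alone) and Stmn3 (-0.33) first, and Nsg2 was higher (adjusted p = 0.0337, and adjusted p = 0.292 with an estimated correlation). This list call ended without untransfected replicate 1 (0.17) or Pbx1 control 2 (0.0605), without untransfected 1 and 2 together (0.459, 1 library left), with the Pbx1 control group alone (0.0936) and without dense genes (0.0818), and with the Tcf3 control group alone the direction was the opposite (0.764). Of the E-protein and Id genes 3 of 7 were lower, Tcf4, Tcf12 (-0.17) and Id4 (adjusted p = 0.0466, and adjusted p = 0.292 with an estimated correlation), which ended without untransfected 1 (0.066) or 3 (0.257), Pbx1 control 2 (0.0605), Tcf3 control 2 (0.0668) or Tcf4 control 3 (0.0601), with the Tcf3 control group alone (0.717), a filter at 50 (0.0514) or a pseudocount of 4 (0.0506), and without dense genes (0.0599). In the hypoxia and glycolysis list 7 of 24 were lower, among them Slc2a1 (-0.53), Slc2a3 (-0.61) and Pfkfb3 (-0.40), and Adm (0.54) and Higd1a were higher (adjusted p = 0.0466, and adjusted p = 0.461 with an estimated correlation). This call ended without untransfected 3 (0.682), Pbx1 control 2 (0.0605) or 3 (0.0538), Tcf3 control 2 (0.0668) or Tcf4 control 1 (0.0535), with the Pbx1 (0.358) or the Tcf3 control group alone (0.692) or a pseudocount of 4 (0.0506). Among the members named with values, calls ended with the Pbx1 control group alone for Mog (0.121), Rsph1 (0.134), Gad2 (0.857), Stmn3 (0.0738), Slc2a1 (0.0945) and Pfkfb3 (0.758), and with the Tcf3 control group alone for Tgfbi (0.0949), Gad2 (0.286), Tcf12 (0.643) and Pfkfb3 (0.479).

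The remaining 11 lists were not called between control siRNA and untransfected cells, with adjusted p from 0.0955 for the astrocyte list to 0.934. Pbx4 was higher and Pknox2 (-0.30) and Pbx1 were lower among TALE genes. Of the astrocyte and quiescent stem cell genes 6 of 24 were higher and 1 lower, of the activated stem cell genes 3 and 3 of 17, of the Wnt genes 4 and 3 of 14, and of the extracellular matrix genes 4 and 5 of 25. Dtx1 (0.49) was higher and Rbpj (-0.25), Hey1 and Notch1 were lower in the Notch list. Creld2 (0.28), Sdf2l1 and Slc3a2 were higher and Atf3 lower among stress response genes. Sox6 (-0.34) was lower among oligodendrocyte precursor genes, Kdr among endothelial and mural genes, Ptch1 among Hedgehog genes, and Atf3, Fosl2 and Klf4 among immediate early genes. Of the 154 list members called in this comparison, 65 kept the call with each library left out. The call was lost for 50, 51 and 28 without untransfected replicates 1, 2 and 3, for 11, 14 and 13 without Pbx1 controls 1, 2 and 3, for 19, 6 and 17 without Tcf3 controls 1, 2 and 3, and for 16, 13 and 7 without Tcf4 controls 1, 2 and 3.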

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

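The fits without the untransfected libraries, without untransfected replicates 1 and 2, with library weights, with averaged replicate pairs, with the trend on value per exon base removed and without dense genes, and the E-protein list without its targeted gene, were chosen after results were seen. All fits use limma, and the cause was not tested for the moved values below unless stated. A count test, planned only for raw read counts, was not run: where 1 read is worth under 1, 2 read numbers can share 1 value. TMM scaling, both filters, both pseudocounts, the trend fit and the density filter left every count within 1.5 times.

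Counts follow in the order Pbx1, Tcf3 and Tcf4 siRNA; the differences Tcf3 and Tcf4, Pbx1 and Tcf3, Pbx1 and Tcf4; and the overlaps in that order, 548, 959, 1149; 466, 257, 665; 153, 104, 84 in the report. With the replicate number as a block they were 306, 393, 696; 166, 81, 329; 61, 35, 39. The labels do not say whether replicate numbers pair the libraries. After each group's mean was removed per gene, knockdown and control libraries of the same number correlated at r = 0 to 0.125 across genes. Those of different numbers correlated at -0.163 to 0.093. Not every knockdown library correlated best with the control of its own number (for instance Tcf3 replicate 1, 0.087 with control 1 and 0.093 with control 2). These values leave open whether the numbers pair libraries. The block also ended the hypoxia and glycolysis call between control siRNA and untransfected cells (0.0511). With the libraries of each comparison alone they were 1707, 1616, 3061; 1425, 865, 2294; 459, 368, 384. Without the untransfected libraries they were 1499, 2353, 2426; 1559, 984, 1886; 534, 417, 302. With library weights they were 2098, 1938, 3599; 1811, 1101, 2877; 560, 442, 448. With the closest replicate pairs averaged, which leaves fewer libraries, they were 209 and 555 for Pbx1 and Tcf4; 186, 80, 214; 83, 47, 26. With 1 library left out, also fewer libraries, they ranged over 202 to 426, 339 to 612, 624 to 809; 219 to 411, 90 to 225, 320 to 680; 67 to 110, 44 to 90, 43 to 68. The 3779 genes between control siRNA and untransfected cells became 2341 with the 12 libraries of the comparison alone, 1567 with the Pbx1 control group alone, 1724 without untransfected replicates 1 and 2 (1 untransfected library left, the spread taken from other groups) and 1020 with library weights, and 2748 to 5254 with 1 library left out.

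Of 285 calls of named genes, 169 kept their direction and call in every alternative. Of 34 list calls 0 did: an estimated correlation ended 33, and the E-protein and Id list with Tcf4 siRNA ended without Tcf4 (0.126, estimated correlation). Between control siRNA and untransfected cells, the sign was reversed for Pfkfb3 with the Tcf3 control group alone (0.084), Bmpr1a without untransfected replicates 1 and 2 (0.001), Tgif1 with the Tcf4 control group alone (-0.28), and the neuroblast and neuron list with the Tcf3 control group alone (adjusted p = 0.764); the cause was not tested. At these depths changes in genes with values near 10 rest on few reads.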

Other observations

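The pathway terms, the clock genes and every test in this part except the splits of libraries in its last paragraph were chosen after results were seen.

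Among 274 pathway terms tested with camera, several metabolic terms were higher with Tcf4 siRNA at the preset correlation. The terms given here did not hold with an estimated correlation. Carbon metabolism was higher, with 14 of 94 genes rising and 2 falling (adjusted p = 3.33e-07, and adjusted p = 0.327 with an estimated correlation). Propanoate metabolism was higher with 8 of 30 rising (adjusted p = 3.33e-07, and adjusted p = 0.173 with an estimated correlation), as was degradation of the branched amino acids valine, leucine and isoleucine with 8 of 44 (adjusted p = 1.28e-05, and adjusted p = 0.0998 with an estimated correlation). With Tcf3 siRNA the Fanconi anemia pathway, which repairs DNA crosslinks, was lower with 12 of 51 falling (adjusted p = 1.9e-06, and adjusted p = 0.197 with an estimated correlation). Aminoacyl-tRNA biosynthesis was lower too, with 5 of 44 falling (adjusted p = 0.00095, and adjusted p = 0.217 with an estimated correlation). With Pbx1 siRNA DNA replication had the smallest camera adjusted p and was lower, with 3 of 35 falling (adjusted p = 6.09e-09, and adjusted p = 0.518 with an estimated correlation). DNA replication also came first with Tcf3 siRNA, with 10 of 35 falling (adjusted p = 3.28e-09, and adjusted p = 0.198 with an estimated correlation). Axon guidance genes were higher with Pbx1 siRNA, with 16 of 158 rising and 2 falling (adjusted p = 0.00107, and adjusted p = 0.518 with an estimated correlation).

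Genes of the circadian clock moved with Pbx1 siRNA. Arntl (Bmal1) rose by 0.43 and its partner gene Npas2 by 1.383, and Per3 (-1.06), the repressor gene Nr1d2 (-0.69, limma adjusted p = 1.96e-06) and the output genes Hlf (-0.65) and Tef (-0.455) fell. Clock itself fell by 0.48, against the direction of its arm. Over 16 clock genes the mean change, signed so that a higher Arntl arm and a lower Per arm count as positive, was 0.414 (SE 0.112 over genes), with 14 in that direction and 8 called in it, and it was -0.127 with Tcf3 and 0.077 with Tcf4 siRNA.

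A response shared by every knockdown does not account for all of these changes, since 6 of the 9 genes called with Pbx1 siRNA differed from both other knockdowns. Of the other 3, Npas2 also rose with Tcf3 siRNA (0.607, adjusted p = 0.0343), with an adjusted p of 0.111 for its difference of 0.776, Cry1 also rose with Tcf4 siRNA (0.377, adjusted p = 0.00275), and Nfil3 did not differ from Tcf4 siRNA (adjusted p = 0.451). A first form of this test, the largest mean signed change in another knockdown (0.077), was undecided and was replaced, and the 9 genes were chosen by their call with Pbx1 siRNA. They did not come from a single deviating library either, as the mean signed change was 0.393 at the lowest with 1 library left out. Collection at different times of the day could also move clock genes, and the labels give a time for 0 libraries, so it cannot be told.

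The lower G1/S phase genes with Pbx1 and Tcf3 siRNA might reflect fewer cycling cells, which was taken to lower the G2/M median by at least 0.5 of the G1/S median. The ratio of the G2/M to the G1/S median change was 0.633 with Pbx1 siRNA (bootstrap range 0.471 to 0.8) and 0.448 with Tcf3 siRNA (0.301 to 0.605), ranges that both include 0.5 and leave this open, and it was split by knockdown after the first ratios were seen. The median change of G2/M genes was smaller than that of G1/S genes with both siRNAs. A permutation over genes, which are not independent replicates, gave p = 0.0015 with Pbx1 and 1e-05 with Tcf3 siRNA. The value of 1e-05 is the lowest that this permutation could give. Genes within these lists were correlated (estimated at 0.402 for G1/S and 0.659 for G2/M), so the p-values cannot decide against an equal fall of both. The G1/S median minus the G2/M median was -0.056 with Pbx1 and -0.114 with Tcf3 siRNA. It was -0.101 with Tcf4 siRNA (permutation p = 1e-05, again the lowest possible), where G1/S genes did not fall (median 0.009). Such a gap alone therefore does not show how the lower G1/S genes arose. The shallow library Tcf3 knockdown 1 was not the cause, since the median without it was -0.195. With the trend of the dense genes removed the list stayed lower with both siRNAs at the preset correlation (larger adjusted p = 2.09e-14), so the levelling off alone was not the cause of these calls, which end with an estimated correlation in the fit without that step (adjusted p = 0.38 with Pbx1 and 0.40 with Tcf3 siRNA).

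Values per exon base levelled off in abundant genes, with a maximum of 0.757 (Malat1) and a median of 0.076 over 11128 genes. Reads at the same position counted once could cause this and would leave less than counting noise between replicates in dense genes. At means of 100 to 400 the median ratio over 18 replicate pairs was 0.771 in genes at 0.2 or more per exon base. It fell with density, from 1.681 under 0.02 to 0.751 at 0.2 to 0.4, the predicted direction. In that last class only 12 of 18 pairs were under 1 (range 0.416 to 1.765). At means of 400 to 1500 the median was still 1.035 in the densest genes, so this cannot tell. A transformation that compresses high values would act whatever the gene length; the quotient of dense to sparse genes was 0.905, with 9 of 18 pairs under 0.9, which cannot tell, under a rule tightened after the value was seen. In the shallow library dense genes were higher than in its replicates by a median of 0.085, against 0.002 in sparse genes. No biological explanation was tested.

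Other splits of the same 6 libraries into 3 and 3 called at most 0 genes in the Pbx1 experiment (real split 548), 23 in the Tcf3 experiment (959) and 0 in the Tcf4 experiment (1149) with limma; the real split ranked 1 of 10 in each, and 10 splits are too few for a share under 0.05. For control siRNA against untransfected cells, a fit with the 9 control libraries as a single group called 443 genes and other splits at most 285 (1 of 100). Those splits mix libraries of groups that differ from one another, so the rank is no sound measure of chance for this comparison. The 2341 of the 12 libraries alone come from a fit with a mean for each control group. For the differences, the real splits called 257 (other splits at most 78, 1 of 100) for Pbx1 and Tcf3 and 665 (at most 329, 1 of 100) for Pbx1 and Tcf4. For Tcf3 and Tcf4 the real split called 466 and ranked 2 of 100. The split ahead of it called 1721, exchanges knockdown and control in a whole experiment and so sums both effects. In neither Pbx1 pair was the highest other split such an exchange. Apart from such exchanges, other splits mix knockdown and control libraries within an experiment. The ranks therefore speak to any knockdown effect and do not test whether 2 responses differ.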
